A study of Mus musculus with 2 samples.

How the data were processed

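Per the labels, microRNA sequencing libraries with inserts under 30 nt were made from the gastrocnemius, a calf muscle, of male mouse pups at postnatal day 4. The pups were B6CASTF1/J, first-generation hybrids of a C57BL/6 and a CAST parent. The labels give a single group of 2 libraries, with biological replicate numbers 1 and 2, animal numbers 3 and 4 and separate biosamples, under a shared donor identifier. The libraries are called replicate 1 and replicate 2, as labelled. There was no second condition, so every comparison is between these 2 libraries.

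For each library the authors deposited raw read counts per microRNA gene, in separate columns for both strands, the sense strand and the antisense strand. Per the deposited description files, the assembly was mm10 and the annotation GENCODE M21. The layout of 4 summary lines followed by 2202 genes is that of STAR gene counts, in which reads mapping to several places are set aside. The aligner, its version and the adapter trimming are not given in the sources used here. All 2202 gene identifiers were matched to GENCODE M21, which holds 2207 microRNA genes, and names, coordinates and overlapping host genes were taken from it. No column of another sample was used (0 columns).

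The 4 summary lines name no gene and stayed out of library sizes and tests. For replicate 1 they held 9.97% unmapped, 35.7% multimapping and 2.05% reads outside the annotated microRNA genes in the sense column, with 0 ambiguous reads. For replicate 2 these shares were 8.60%, 45.1% and 3.83%, again with 0 ambiguous reads. In the unstranded column the ambiguous reads came to 6.31% and 11.9%.

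The sense column was used throughout. CPM and shares are relative to all sense reads assigned to microRNA genes in a library, 4458853 in replicate 1 and 3073086 in replicate 2. Shares have exact Clopper-Pearson 95% intervals. The limit that a count of 0 allows was set at 3 counts, which is 0.673 CPM in replicate 1 and 0.976 CPM in replicate 2. The sources used here name no molecular identifiers, and reads amplified by PCR are not independent molecules, so intervals and limits cover counting error only.

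A gene was called detected with at least 10 reads in each library. Log2 ratios are replicate 2 over replicate 1, with a prior count of 1 and effective library sizes from the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. Each gene with at least 10 reads in total was given a two-sided exact binomial test of its reads in the 2 libraries, with Benjamini-Hochberg adjustment. A gene was past the threshold with an adjusted p under 0.05 and an absolute log2 ratio of at least 1. This test compares 2 libraries, not conditions, and measures departure from counting noise only. Many adjusted p-values were too small to be stored, so log2 ratios are given with their 95% counting intervals instead. For the same reason, counts adjusted over a list alone, also given, could hardly differ and add no support. The spread between the libraries was also estimated as the common dispersion of edgeR with both libraries as a single group.

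The results cover 26 lists of microRNA genes for skeletal muscle, heart, imprinted clusters, Hox clusters, families and markers of other cell types. For the 17 lists with at least 3 tested members, the median log2 ratio was placed among 10000 random lists of the same size, matched on deciles of mean log2 CPM. That percentile describes these libraries and is not a p-value. The genes named are the 20 with the highest mean share of reads, every annotated member of the skeletal muscle list, up to 3 members of each other list by mean share, and the 5 with the largest ratio in each direction among genes past the threshold with at least 100 reads. Other genes named were chosen after their values were seen. The groups, tests, lists, rule for named genes and first set of alternatives were fixed before the data were examined.

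Annotated microRNA sequences were searched for 22 nt stretches shared with another annotated microRNA gene on either strand. A search of the whole genome was not run, because no genome sequence was used here. Alternatives were DESeq2 1.42.0 size factors or total reads in place of TMM, other minimum counts, the unstranded column, window lengths of 18 and 25 nt, the edgeR exact test with pooled dispersion, and each library alone. Alternatives added after seeing the data left out the genes sharing a window or the Dlk1-Dio3 list.

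The binomial comparison was tested on simulated data, with Poisson counts for 2 libraries and 416 genes tested. It recovered 85 of 101 genes changed by a log2 ratio of 1.5 and 97 of 97 changed by 3, and called 1 of 218 unchanged genes. The simulated counts had no spread beyond Poisson and the same effective library sizes as the test. These rates therefore do not cover errors of scaling or differences between animals. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.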

Results

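MicroRNA genes were counted in 2 libraries labelled as gastrocnemius of male B6CASTF1/J pups at postnatal day 4, which makes 1 group of 2 labelled biological replicates. The library labelled replicate 1 held 8522350 reads and that labelled replicate 2 held 7240126. Of these, 4458853 reads (52.3%) and 3073086 reads (42.4%) were assigned to microRNA genes on the sense strand, a 1.45-fold difference in depth. The design allows a description of the microRNA content of each library and of how far the libraries differ. The muscle microRNA Mir206 had 652657 reads in replicate 1 and 101 in replicate 2, and the heart-restricted Mir208a had 59 and 29718, so the libraries are named by their labels throughout. The values given for single genes have no further replicates, and log2 ratios are replicate 2 over replicate 1.

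Mir206, a microRNA restricted to skeletal muscle, was the most abundant gene of replicate 1 and held 14.6% of its microRNA reads (95% interval 14.6 to 14.7%). In replicate 2 the same gene held 0.00329% (0.00268 to 0.00399%) and ranked at 204. Mir378a, in an intron of the metabolic coactivator gene Ppargc1b, led replicate 2 with 18.4% of reads and held 5.50% in replicate 1. Mirlet7i followed in replicate 2 with 10.2%, against 5.43% in replicate 1. Mir127 and Mir411 of the imprinted Dlk1-Dio3 domain held 6.04% and 5.84% of replicate 1 but 0.238% and 0.164% of replicate 2.

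Among the other genes with the highest mean share, the endothelial Mir126a held 2.54% of replicate 1 and 6.62% of replicate 2. The smooth muscle gene Mir143 held 2.12% and 4.76%, Mir23a 2.40% and 4.72%, and Mir23b 2.54% and 3.77%. Mir99a held 1.88% and 3.17%, Mir26b 1.35% and 2.40%, Mir139 0.800% and 1.95%, and Mir22 0.636% and 2.70%. The share of Mir335, in an intron of the imprinted gene Mest, went the other way with 3.76% and 0.565%. Shares are relative, and the Dlk1-Dio3 list alone took 32.9% of replicate 1 and 0.973% of replicate 2. Genes that did not change would thus gain share in replicate 2. Relative to TMM sizes, Mir23b, Mir99a and Mir26b had log2 ratios of −0.06, 0.12 and 0.21. Of the genes in this paragraph, only Mir22 (1.46) and Mir335 (−3.36) were past the threshold. The 10 most abundant genes of each library took 54.2% of replicate 1 and 67.9% of replicate 2. The top 20 genes of the libraries shared 11 members.

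The libraries ranked many microRNA genes differently. Of 2202 annotated genes, 341 had at least 10 reads in replicate 1 and 340 in replicate 2, and 299 had them in both. A further 42 genes reached that count in replicate 1 alone and 41 in replicate 2 alone. Across the 299 shared genes, Pearson's r of log2 CPM was 0.675 and Spearman's rho 0.654, and genes are not independent replicates. The median absolute log2 ratio was 1.13, with 163 genes (54.5%) at least 2-fold apart and 69 at least 8-fold apart. The common dispersion of edgeR over the pair was 1.23, a biological coefficient of variation of 1.11. Leaving out the Dlk1-Dio3 list gave r = 0.840.

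**Figure D1:**
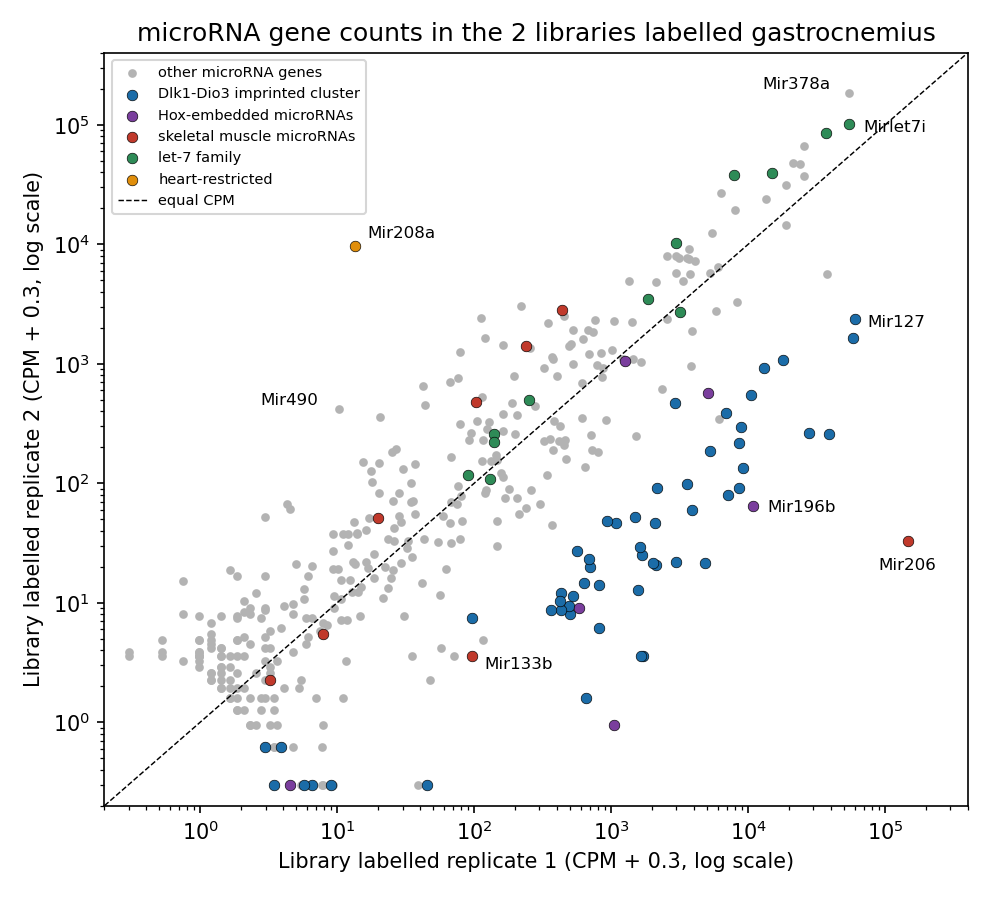
CPM plus 0.3 of each microRNA gene with at least 10 reads in total, in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with lists in colour and a dashed line at equal CPM. Mir206 and the Dlk1-Dio3 genes lie far to the right of the line, and Mir208a, with 59 reads in replicate 1 and 29718 in replicate 2, lies far above it.

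Of 410 genes tested, 72 were higher in replicate 2 and 148 were lower, by the binomial test with Benjamini-Hochberg adjustment. The 5 named for the lowest ratios were Mir206, Mir196a-2, Mir665, Mir380 and Mir410, with log2 ratios from −12.73 to −9.27. The 5 named for the highest were Mir208a, Mir490, Mir34a, Mir215 and Mir200c, with log2 ratios of 8.86, 4.70, 3.80, 3.53 and 3.50. Mir34a (501 and 7414 reads) is a target of p53, and Mir490 (45 and 1275 reads) lies in an intron of the muscarinic receptor gene Chrm2. Of the 148 lower genes, 53 belonged to the Dlk1-Dio3 list. The share of calls that were higher was 32.7% under TMM, 44.3% with DESeq2 size factors (101 of 228) and 54.0% with total reads (135 of 250). Those scalings moved the median log2 ratio of all tested genes by 0.28 and 0.63 from its TMM value of −0.33. With the pooled dispersion of the pair, the edgeR exact test called 0 of 410 genes, and 28 had an unadjusted p under 0.05. That dispersion was estimated from the same pair and includes the difference under test, so the count of 0 does not show that the libraries agree.

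The skeletal muscle list split between the libraries. Its 11 annotated members held 14.7% of replicate 1 (14.7 to 14.8%) and 0.479% of replicate 2 (0.472 to 0.487%), and nearly all of the former was Mir206. Of 8 members tested, Mir206, Mir133b and Mir133a-1 were lower in replicate 2, and Mir208b, Mir499 and Mir486 were higher. Adjusted over the list alone, the count was also 6. Mir206 lies in an exon of the noncoding gene Gm28653 (mm10 chromosome 1, 20679010 to 20679082), with 652657 reads against 101 and a log2 ratio of −12.73 (−13.04 to −12.47). Mir133b, in an exon of the same gene at 20682769 to 20682887, had 427 reads against 10, a log2 ratio of −5.37 (−6.58 to −4.61).

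The microRNAs inside myosin heavy chain genes were higher in replicate 2. Mir208b, in an intron of the slow muscle and cardiac gene Myh7 (chromosome 14, 54975700 to 54975776), had 1068 and 4340 reads, a log2 ratio of 1.93 (1.84 to 2.03). Mir499, in an intron of Myh7b (chromosome 2, 155622880 to 155622958), had 1953 and 8633 reads, a log2 ratio of 2.05 (1.98 to 2.13). Mir486, in an intron of the ankyrin gene Ank1, had 456 and 1468 reads, a log2 ratio of 1.59 (1.44 to 1.75). Mir208a, the only member of the heart-restricted list, lies in an intron of the cardiac gene Myh6 (chromosome 14, 54949060 to 54949142). It held 0.00132% of replicate 1 and 0.967% of replicate 2 (0.956 to 0.978%), a log2 ratio of 8.86 (8.52 to 9.28). Mir208a reads were 0.0552 times those of Mir208b in replicate 1 and 6.85 times in replicate 2.

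Mir1a and Mir133a, muscle microRNAs with near-identical copies at several loci, had few counted reads in either library. Mir1a-2 had 87 reads in replicate 1 and 156 in replicate 2, Mir1a-1 had 13 and 6, Mir133a-1 had 34 and 16, and Mir133a-2 had 2 in each. Mir1b had 5 and 1, and Mir133c had 0 in both, which allows up to 0.673 and 0.976 CPM. These counts are uncertain because Mir1a-1, Mir1a-2, Mir1b, Mir133a-1 and Mir133a-2 share a 22 nt stretch with another annotated microRNA gene. The list's median log2 ratio of −0.17 over 8 tested members lay at the 60.4th percentile of random lists. With at least 100 reads in total, Mir1a-1 and Mir133a-1 dropped out of the list. The median of the members left then lay between Mir1a-2 (0.75) and Mir486 (1.59), at percentile 98.8. The median over all 8 turned to 0.11 with DESeq2 size factors and 0.45 with total reads. Under both, Mir133a-1 lost its call and Mir1a-2 was higher, at 1.02 and 1.37.

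All 53 tested genes of the Dlk1-Dio3 imprinted cluster were lower in replicate 2. This domain, whose microRNAs are transcribed from the maternal chromosome, held 32.9% of replicate 1 (32.9 to 33.0%) and 0.973% of replicate 2 (0.962 to 0.984%). The median log2 ratio was −5.98 and was unchanged with 5 genes without reads in replicate 2 set at 3 counts. It lay at percentile 0 of the random lists, and the count adjusted over the list alone was 53. Mir127 (chromosome 12, 109592846 to 109592915) had 269519 and 7304 reads, a log2 ratio of −5.29 (−5.33 to −5.26). Mir411 had a log2 ratio of −5.78, Mir431 of −7.35 and Mir487b of −7.87. Mir665 and Mir380 each had 10 reads in replicate 2, against 7684 and 7421. All 53 calls were also made with DESeq2 size factors and with total reads. The library with few of these reads was also the one with 101 reads of Mir206 and 29718 of Mir208a.

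**Figure D2:**
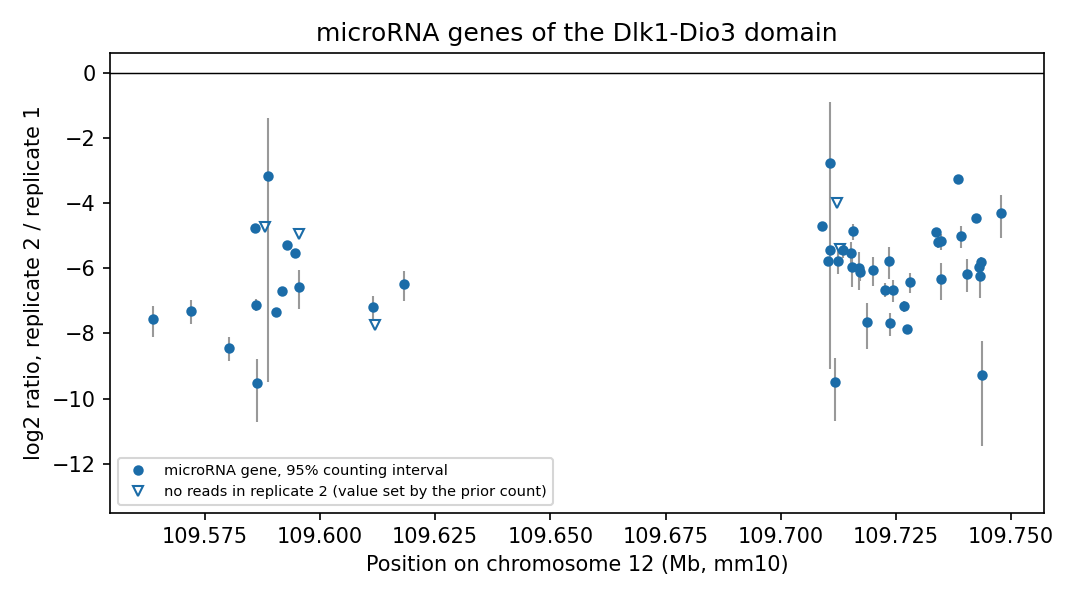
Log2 ratio of replicate 2 over replicate 1 (y axis) for 53 microRNA genes of the Dlk1-Dio3 domain against their position on mm10 chromosome 12 in megabases (x axis), with bars for 95% counting intervals and open triangles for 5 genes without reads in replicate 2. Every gene drawn, from 109563692 to 109747960, lies under 0.

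Mir483, Mir675 and Mir335, at other imprinted loci, were also lower in replicate 2. Mir483, in an intron of the fetal growth factor gene Igf2 (chromosome 7, 142654924 to 142654996), had 27493 and 1066 reads, a log2 ratio of −4.78 (−4.87 to −4.69). Mir675, in an exon of H19 (142577064 to 142577147), had 211 and 6 reads, a log2 ratio of −5.01 (−6.69 to −4.08). The H19-Igf2 list held 0.621% of replicate 1 and 0.0349% of replicate 2, and 2 of 2 members were lower, also adjusted over the list alone. Mir335 in Mest (chromosome 6, 30741299 to 30741396) had 167500 and 17375 reads, a log2 ratio of −3.36 (−3.38 to −3.34). Of 8 tested genes of the Sfmbt2 intronic cluster, 4 were lower, Mir467e and Mir669o among them with a log2 ratio of −1.11 each, and Mir467d stood at 0.29. Its median log2 ratio was −0.95 (−0.67 with DESeq2 size factors and −0.32 with total reads), at percentile 46.8, with 0 members higher. The cluster held 0.130% and 0.159% of reads. Mir467d, Mir467e and Mir669o share 22 nt stretches with other microRNA genes, and the cluster's lower calls came to 2 with DESeq2 size factors and 0 with total reads.

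MicroRNAs embedded in the Hox clusters, which pattern the body axis, were mostly lower in replicate 2. The list held 1.88% of replicate 1 (1.87 to 1.89%) and 0.170% of replicate 2 (0.166 to 0.175%), and 5 of 6 members were lower, also adjusted over the list alone. Mir196b, in an exon of Hoxa9 (chromosome 6, 52230081 to 52230165), had 48288 and 197 reads, a log2 ratio of −8.02 (−8.24 to −7.83). Mir196a-2, in an intron of Hoxc5 (chromosome 15, 102973350 to 102973434), had 4714 and 2 reads, a log2 ratio with an interval of −14.34 to −9.44. It shares a 22 nt stretch with another microRNA gene. Mir10b, in an intron of Hoxd3 and Hoxd4, had a log2 ratio of −3.79, and Mir10a was not past the threshold at −0.88. The median of −5.52 lay at percentile 0.810, and was −5.20 with the 1 gene without reads in replicate 2 set at 3 counts. Mir206 was low (101 reads) and Mir208a high (29718 reads) in the library with few Hox microRNAs.

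**Figure D3:**
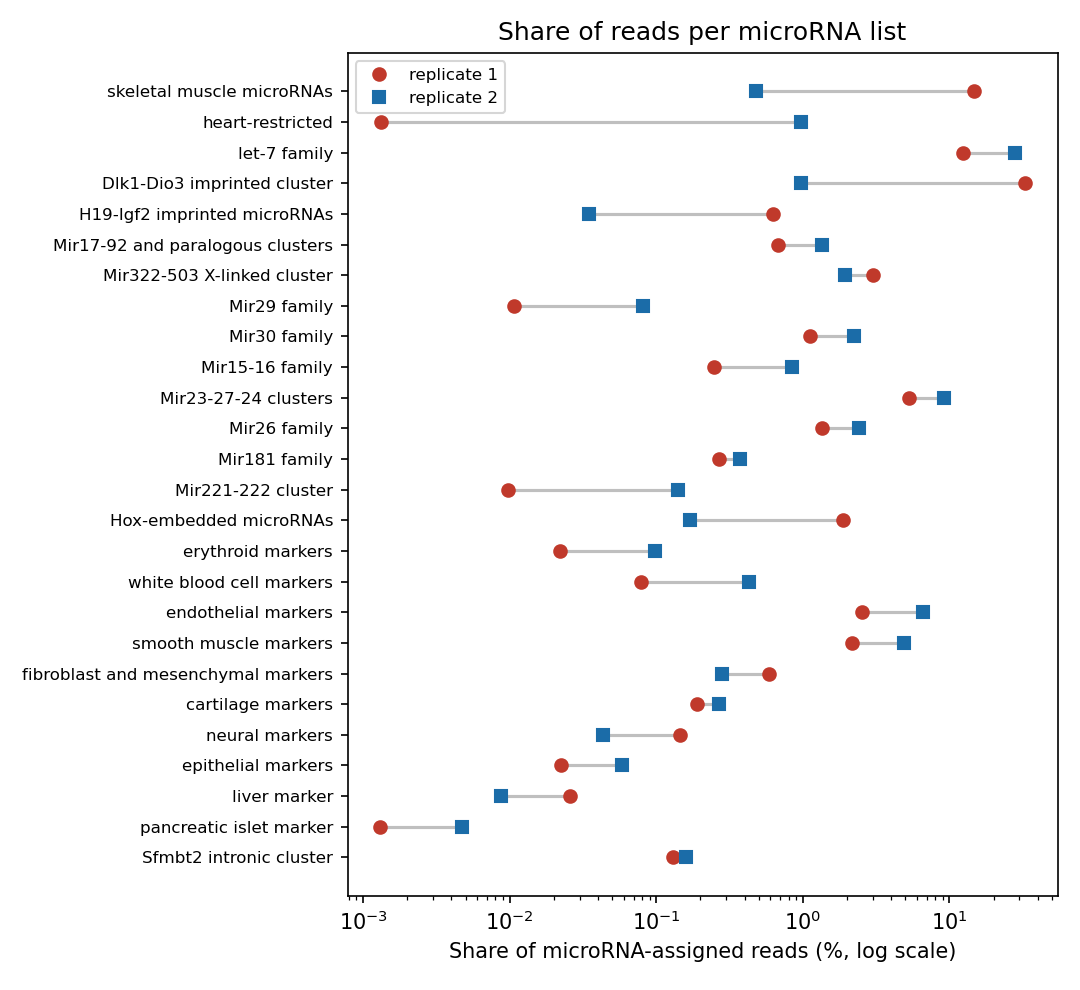
Share of microRNA reads in percent (x axis, log scale) of each list (y axis) in replicate 1 (red circles) and replicate 2 (blue squares). The Dlk1-Dio3 list stood at 32.9% and 0.973%, the let-7 family at 12.3% and 28.2%, and heart-restricted Mir208a at 0.00132% and 0.967%.

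The let-7 family, whose mature forms accumulate during differentiation, held 12.3% of replicate 1 and 28.2% of replicate 2. Relative to TMM sizes, 2 of 12 members were higher in replicate 2, Mirlet7b at a log2 ratio of 1.64 and Mirlet7e at 1.16, also adjusted over the list alone. Mirlet7i stood at 0.28, Mirlet7g at 0.57 and Mirlet7d at 0.79, all under the threshold. The list's median of 0.28 lay at percentile 76.1. Mirlet7a-1, Mirlet7a-2, Mirlet7c-1, Mirlet7c-2, Mirlet7f-1 and Mirlet7f-2 share stretches with other microRNA genes, so their counts and the list's median are uncertain. Their log2 ratios ran from −0.89 to 0.37, and those of the other members from −0.84 to 1.64. With DESeq2 size factors 3 members were higher and with total reads 5. The higher let-7 share stood in the library with the low share of Mir206 and the high share of Mir208a.

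Of 13 tested genes of the growth-promoting Mir17-92 cluster and its paralogs, 4 were higher in replicate 2 and 1 was lower. Mir93 was higher with a log2 ratio of 1.26, Mir92-1, which shares a 22 nt stretch with another gene, was just under the threshold at 0.995 and Mir17 stood at −0.75. The list held 0.680% and 1.34% of reads, and its median of 0.95 lay at percentile 99.4. With DESeq2 size factors 7 members were higher and 1 lower, and with total reads 7 were higher and 0 lower. The X-linked cluster of Mir322 and its neighbours, linked to cell cycle exit in muscle, had 6 of 7 members lower, Mir351 at −1.94, Mir542 at −1.29 and Mir322 at −1.02. It held 3.02% and 1.93% of reads, with the median at percentile 7.11. Mir322 lost its call with DESeq2 size factors at −0.74, which left 5 members lower, and with total reads, at −0.39. With total reads Mir542 lost its call too, at −0.66, which left 4. Counts adjusted over the list alone were 5 for Mir17-92 and 6 for the Mir322 cluster.

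Other families differed in part. In the Mir30 family 3 of 6 members were higher in replicate 2, while Mir30a, Mir30d and Mir30e stood at −0.05, 0.46 and 0.40; its shares were 1.13% and 2.22%. In the Mir15-16 family Mir15b (2.04) and Mir497 (1.86) were higher, 1 of 6 was lower and Mir15a stood at 0.50, with shares of 0.249% and 0.845%. In the Mir29 family, repressors of collagen genes, Mir29a was higher at 2.69, Mir29c stood at 0.30, and shares were 0.0107% and 0.0816%. Both members of the Mir221-222 cluster were higher, Mir221 at 3.39 and Mir222 at 2.27, with shares of 0.00980% and 0.142%. None of the 6 tested genes of the Mir23-27-24 clusters passed the threshold, with Mir23a at 0.35 and shares of 5.29% and 9.22%, though 2 were higher with DESeq2 size factors and 3 with total reads. With total reads, higher members numbered 5 in Mir30, 4 in Mir15-16, where the lower call was lost, and 2 in Mir29. Medians lay at percentiles 94.975 for Mir30, 94.5 for Mir15-16, 73.7 for Mir29 and 83.4 for Mir23-27-24. Mir30c-1 (higher), Mir16-2 (the lower Mir15-16 gene) and Mir29c, among others, share 22 nt stretches with other microRNA genes, so their ratios are uncertain.

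In the Mir26 family Mir26b, which held nearly all reads (1.35% and 2.40% for the list), stood at 0.21. Mir26a-1 and Mir26a-2, which share a 22 nt stretch with another microRNA gene and had few reads, were lower, the latter at a log2 ratio of −1.07, and neither call held with total reads. The Mir181 family held 0.266% and 0.372% of reads, with 1 of 6 members lower, and Mir181d stood at −0.07. Its median of −0.18 turned to 0.10 with DESeq2 size factors and 0.44 with total reads, and its lower call was lost under both, with 1 member higher with total reads. Percentiles were 17.4 for Mir26 and 67.2 for Mir181. Adjusted over the list alone, the counts were 3 for Mir30, 3 for Mir15-16, 1 for Mir29, 2 for Mir221-222, 0 for Mir23-27-24, 2 for Mir26 and 1 for Mir181, as over all genes.

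Most markers of blood cells were higher in replicate 2, the library with 0.00329% of Mir206 and 0.967% of Mir208a. The erythroid genes Mir451a and Mir144 had log2 ratios of 1.39 and 2.22, and the list held 0.0220% and 0.0979% of reads. Of 5 white blood cell markers, Mir155 (3.15), Mir150 (2.78) and Mir146 (1.79) were higher and 1, the myeloid gene Mir223, was lower at −1.16. That list held 0.0793% and 0.429% of reads with a median of 1.79 at percentile 98.5, and the lower call was lost under both other scalings. The endothelial Mir126a stood at 0.75 and the smooth muscle genes Mir143 and Mir145a at 0.54 and 0.88, all under the threshold, with list shares of 2.54% and 6.62% and of 2.17% and 4.90%. Mir126a passed it under both other scalings, at 1.03 and 1.38, and so did Mir145a at 1.16 and 1.51, while Mir143 passed it with total reads at 1.17.

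The tested mesenchymal markers and 4 of 5 tested neural markers were lower in the same library. The fibroblast genes Mir214, Mir199b and Mir199a-2 had log2 ratios of −1.68, −2.32 and −4.38, 3 of 3 lower, with shares of 0.591% and 0.281%. Of 13 annotated neural markers 5 were tested. The Mir9 and Mir124a genes, each annotated at several loci, had 0 counted reads in both libraries. Reads mapping to several of those loci would be set aside, so these counts do not show absence. Of the 5 tested 4 were lower, Mir128-1 at −2.11, Mir128-2 at −3.66 and Mir338 at −2.15 among them. Mir219a-1, with 8 and 25 reads, was higher at 1.44, and list shares were 0.145% and 0.0434%. The cartilage genes Mir140 and Mir455 stood at 0.75 and −0.91, both under the threshold, with shares of 0.190% and 0.267% and a median of −0.08 that turned to 0.20 and 0.55 under the other scalings. Under these, Mir140 passed the threshold at 1.03 and 1.38. Mir199a-2, Mir199b, Mir128-1 and Mir128-2 share stretches with other microRNA genes. Percentiles were 5.88 for the fibroblast and 8.46 for the neural list.

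Markers of other organs were rare in both libraries. The epithelial list held 0.0223% and 0.0587% of reads, and 3 of 7 members were higher, Mir200c at 3.50 among them, while Mir203 stood at −0.996 and Mir205 at 0.10, under the threshold. Under both other scalings 5 of 7 were higher. Its median lay at percentile 92.3. The liver gene Mir122 held 0.0258% and 0.00875%, lower at −2.18, and the islet gene Mir375 held 0.00130% and 0.00472%, higher at 1.22. Adjusted over the list alone, the counts were 2 for erythroid, 4 for white blood cell, 0 for endothelial, smooth muscle and cartilage, 3 for fibroblast, 5 for neural, 3 for epithelial, 1 for liver, 1 for islet and 4 for Sfmbt2 genes, and 1 for Mir208a, as over all genes.

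Several abundant genes were visible in the sense column alone. Mir378a had 245195 and 566450 sense reads but 0 in the unstranded column, and Mir126a had 113331 and 203314 against 5 and 14. These are among 64 genes that overlap an annotated microRNA gene on the opposite strand. Together they held 537681 and 865010 sense reads, and 32 and 15 reads in the unstranded column. Of the 2202 genes, 1032 share a 22 nt stretch with another annotated microRNA gene, and they held 1.42% of replicate 1 and 1.65% of replicate 2. Among detected genes, the median count in replicate 1 was 254 for the 53 sharing a stretch and 1474.5 for the rest, and in replicate 2 it was 204 and 416.5.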

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

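The restriction to genes without an opposite-strand neighbour was chosen after the strand columns were seen. Reads antisense to microRNA genes, which enter no comparison of the report, were above the 3 counts that a count of 0 allows. Outside the 64 genes that overlap a microRNA gene on the other strand, there were 57 antisense reads in replicate 1, over 21 genes, and 61 in replicate 2, over 17 genes. Mir434 led in replicate 1 with 12 reads and Mir122 in replicate 2 with 13 reads, both named after their values were seen. No explanation was tested for these reads.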

How the results depend on the processing

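The tests without the Dlk1-Dio3 list and without genes sharing a 22 nt stretch were chosen after the data were seen. The medians of the muscle, Mir181 and cartilage lists changed sign under both other scalings, and higher calls went from 32.7% to 54.0% with total reads. Apart from each library alone and from values that scaling cannot change, 410 of 471 alternative values kept their range or side of the threshold, 19 moved, 24 newly passed it and 18 no longer did. A share kept its range if it stayed within 1 SD of the mean of the 2 libraries. That range was wide, as for Dlk1-Dio3 with a mean of 16.9% and an SD of 22.6%. Few alternatives could leave it, so the count of 410 does not measure how robust the shares are. Genes detected in both libraries came to 521 with at least 1 read and 186 with at least 100. Pearson's r was 0.852 with at least 1 read in both and 0.840 without the Dlk1-Dio3 list. The edgeR exact test with pooled dispersion called 0 of 410 genes where the binomial test called 220; it adds the spread between the 2 libraries, estimated from the same pair, to counting noise. With at least 100 reads in total, which leaves fewer genes, the white blood cell list moved to percentile 97.3. The muscle list, which lost Mir1a-1 and Mir133a-1 at that limit, moved to 98.8. Reads of genes sharing a stretch came to 43.5% with 18 nt and 0.659% with 25 nt, against 1.53% with 22 nt (means of 2 libraries). Assigned reads came to 38.3% in the unstranded column, against 47.4%. With each library left out, shares ran from 0.479 to 14.7% for muscle, 12.3 to 28.2% for let-7, 0.973 to 32.9% for Dlk1-Dio3, 0.170 to 1.88% for Hox and 0.00132 to 0.967% for Mir208a, detected genes from 340 to 341, and the 20 named abundant genes from 70.1 to 77.4%. Of 84 named genes, calls were kept by 72 with DESeq2 size factors and 64 with total reads, and of 76 with unstranded reads, by 68; the cause was not tested, though scaling shifts all ratios alike. The search for repeats in the whole genome was not run, and no paired analysis was possible because there is 1 group. Depth limits genes near 0.673 and 0.976 CPM.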

Other observations

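Among the tests here, only that of Mir490 was set out before its value was seen, with Mir208a already known; the others were chosen after the results were seen. Outside the lists, 105 genes were past the threshold, 44 higher and 61 lower in replicate 2. Mir107, in an intron of the pantothenate kinase gene Pank1, had 973 reads in replicate 1 and 9282 in replicate 2, a log2 ratio of 3.16 (3.07 to 3.26). Its paralog Mir103-2, in Pank2, had 74 and 59 reads and was not past the threshold at −0.41 (−0.94 to 0.10). Reads that also map to the other annotated Mir103 gene would be set aside, so the contrast with Mir107 is uncertain. Mir185 had 717 and 4389 reads (2.52) and Mir31 had 67 and 459 reads (2.67). Mir107, Mir103-2, Mir185 and Mir31 were named after their values were seen.

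Mir206 and most Hox microRNAs were far lower in replicate 2, while heart-restricted Mir208a was far higher. A difference in depth is argued against by replicate 1 thinned to the depth of replicate 2, which kept 449990 reads of Mir206 against 101. Gastrocnemius RNA mixed with other RNA was examined in Mir206, the 3 Mir196 genes and Mir615, picked after their low values were seen. Their median level was 0.0616% of replicate 1 (Mir196a-2, upper counting bound 0.222%), under the 5% set for such a mixture. The bounds of all but Mir196a-1 were under 5% too. For its 19 and 0 reads, the 95% counting interval of the ratio allows up to 31.1%. Mir10b (5077 and 567 CPM) and Mir10a (1266 and 1063 CPM), left out of the 5, lay above 5%. As genes picked for being low, the 5 argue only against a gastrocnemius portion of 5% or more in replicate 2. A smaller portion stays open. As a hypothesis, the library labelled replicate 2 may come from another tissue than its label says: Mir490 in Chrm2, a receptor gene of heart and smooth muscle, was higher by a log2 ratio of 4.70 (4.31 to 5.20), which was set out in advance for heart as that tissue and would not be required of others. Heart is a candidate source only, from a list of 1 gene, Mir208a, with 29718 reads in replicate 2 and 59 in replicate 1; skeletal muscle also expresses Mir208b and Mir499, which stand on the muscle list. A difference between the animals stays open and untested, and no other tissue was compared.

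MicroRNAs of the imprinted Dlk1-Dio3 and H19-Igf2 loci and Mir335 in Mest were lower in replicate 2, and 4 of 8 genes of the Sfmbt2 cluster were lower and 0 higher, with a median of −0.95 at percentile 46.8 and 0 lower calls with total reads. For sequence-dependent bias in library preparation, neighbouring genes of 46 groups outside Dlk1-Dio3 were compared. Their log2 ratios had a spread of 1.01 within groups against 2.08 when permuted (permutation p = 0.0001, the smallest that 10000 permutations give). Neighbours thus had like ratios in those groups. Some groups, such as the Sfmbt2 cluster, hold genes that share stretches, where such a bias could also give like ratios. With Dlk1-Dio3 left out, the test cannot decide on bias at the imprinted genes. The difference was not confined to the Dlk1-Dio3 domain, since the median log2 ratio was −4.78 over Mir483, Mir675 and Mir335, genes already known to be lower when that test was chosen. An older animal could lower fetal microRNAs and raise let-7, but the let-7 list stood at percentile 76.1, which decides nothing. Some let-7 genes share stretches with other microRNA genes, so the list's median and percentile are uncertain. Both libraries are labelled postnatal day 4, and no animal of another known age was compared. For the imprinted microRNAs, age and tissue of origin cannot be told apart in 1 library. A difference between the animals remains untested.

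Mir1a and Mir133a, abundant microRNAs of skeletal and heart muscle, had few counted reads in both libraries. As a hypothesis, counting that sets aside reads mapping to several places may remove them: in 23 groups of neighbouring genes with a gene of at least 100 reads, those sharing a 22 nt stretch had a median of 0.0401 times the reads of neighbours sharing none, below 1 in 17 groups, above 1 in 5 and tied in 1 (exact two-sided sign test over the 22 groups without a tie, p = 0.0169). Those groups do not include Mir1a or Mir133a, whose neighbours all share stretches, and the search covered annotated microRNA genes, not the genome. Multimapping reads were 35.7% and 45.1% of the libraries. No biological explanation was tested.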
